A study of Mus musculus with 30 samples.

How the data were processed

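Total RNA from both ventricles of female mice was measured on 30 Affymetrix arrays, 5 per group in 6 groups. Group and replicate were taken from the sample labels, and the design text names the 5 arrays of a group biological replicates. The deposited values are log2 expression values, 1 per row and array, made with RMA in Affymetrix Expression Console 1.1 according to the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarizes the probes of a row by median polish. The log base was taken from the definition of RMA and from the range of the values. The 20 surgical arrays and the 10 running arrays had different medians, from which separate normalization was inferred, and the notes used here do not state it. The number of arrays limits the precision: the median SE of a log2 fold change was 0.069, and 0.097 for a difference between 2 effects.

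The table held 35556 rows. Of these, 21789 were paired with 1 gene symbol, 1621 with several and 12146 with none listed. Rows with 1 symbol were tested, and of them 21698 were matched by Entrez ID to a gene table of the mouse genome, with 0 symbols changed by it. For the 999 genes with more than 1 row, the row with the highest mean over all arrays was used, which left 19938 genes. No filter on dim genes was used. A second row of Ppargc1a measured -0.20 in CH and did not pass (adjusted p = 0.119).

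Group means were fitted over all 30 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests (eBayes, 24 residual and 4.25 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 19938 genes of each comparison at a threshold of 0.05. The comparisons were HF with HF_sham, CH with CH_sham and Run with Sed, the 3 differences between these effects, and CH_sham with HF_sham. No controls are shared between the 3 main comparisons. Errors of fold changes are SE and those of group means SD. Intervals are at 95% confidence.

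A fixed set of 38 gene lists, with 558 of 594 listed members measured, was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Fry was also run in a form that counts changes in either direction, which enters only the ranges given with the replicate block. Members were counted as rising or falling at adjusted p 0.05 over all genes, and also adjusted over the list alone. The mean log2 value over a list was compared between groups by an exact two-sided permutation over the 252 splits of 5 against 5, where 0.00794 is the smallest possible p.

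Genes were named by a fixed rule. It took the 6 largest rises and 6 largest falls past the threshold whose group values did not overlap, skipping predicted genes, such as Gm10635 in HF (-1.55). It also took up to 4 members with the smallest p of each list that was called or had at least 3 members past the threshold, a panel of 14 cardiac genes in every comparison, and the 5 largest positive and negative differences between effects. Cpt1b of this panel was not analysed here, since its row lists several symbols. Members of the unfolded protein, immediate-early and clock lists given beyond the rule, and the genes called without CH replicate 5, were chosen after their values were seen. Comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except for 1 setting chosen afterwards, which leaves out CH replicate 5, CH_sham replicate 1 and Run replicate 2 together.

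The alternatives were quantile normalization applied again, centring each array on its median, leaving out genes with a mean under the median of all genes, testing all rows, averaging the rows of a gene, eBayes with trend and robust estimation, array weights, fitting the compared arrays alone, the replicate number as a block, adjusted p 0.01, a fold of at least 1.5, and leaving out each array in turn. The procedure was tested on simulated data with 100 genes changed 1.25-fold and 100 changed 1.5-fold in each main comparison. It recovered 71 and 97 of them for HF, 69 and 99 for CH and 70 and 97 for Run. Unchanged genes made up 3.4%, 11.6% and 1.2% of the calls, so the CH simulation exceeded the nominal 5%. Of 3 lists shifted by 0.15 in the Run simulation 3 were recovered, and 1 other list was called. The simulated noise was drawn independently for each gene. The simulation therefore cannot test the preset correlation of 0.01 between the genes of a list.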

Results

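Gene expression was measured by microarray in total RNA from both ventricles of female C57Bl6/J mice, in 6 groups of 5 animals. Pressure overload was produced by transverse aortic constriction, a surgical narrowing of the aortic arch, and these hearts (CH) were set against sham-operated controls (CH_sham). Hearts of mice with heart failure (HF) had sham-operated controls of their own (HF_sham), and how heart failure was produced is not stated in the labels. All 4 surgical groups were 3 months old. The remaining groups were labelled 2 months old and comprised mice with 2 months of voluntary wheel training (Run) and sedentary controls (Sed). These labels of age and training cannot both hold at collection, so the age of the Run and Sed mice at collection is uncertain. Differences between a surgical effect and the running effect also span age, surgery and experiment. Array medians ran from 7.18 to 7.24 on the log2 scale in the 20 surgical arrays and from 6.79 to 6.84 in the 10 arrays of the running experiment. Expression levels were therefore not compared directly between the surgical and the running arrays. No pair of the 30 arrays held identical values.

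Heart failure was first compared with its sham group to find the genes that differed in the failing ventricles. Postn, which encodes the matricellular protein periostin, rose 6.02-fold, with a log2 fold change of 2.59 ± 0.20 (SE, n = 5 arrays per group, adjusted p = 5.9e-10). Its level was 9.83 ± 0.18 (SD) in HF_sham and 12.42 ± 0.21 in HF. The other rises taken by the naming rule were Serpina3n, an acute-phase protease inhibitor, at 2.54 ± 0.33, Thbs4 at 2.36 ± 0.28, the skeletal alpha-actin gene Acta1 at 2.21 ± 0.15, Col8a1 at 2.17 ± 0.15 and the beta myosin heavy chain gene Myh7 at 2.11 ± 0.24. The falls were led by the carboxylesterase gene Ces1d, whose level went from 11.34 ± 0.04 in HF_sham to 9.42 ± 0.21 in HF, a 3.8-fold drop (adjusted p = 4.28e-09). Ucp3, a mitochondrial uncoupling protein of muscle, had a log2 fold change of -1.41 ± 0.21, Pla2g5 of -1.21 ± 0.11, Rgs7 of -1.12 ± 0.12, Retnla of -1.07 ± 0.17 and Inmt of -1.0 ± 0.15.

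Across the fixed panel of cardiac genes, the natriuretic peptide genes Nppa and Nppb rose in HF by 1.78 ± 0.14 and 1.34 ± 0.17 log2 units. Col1a1 and Ccn2, a collagen and a matricellular growth factor, rose by 0.79 ± 0.11 and 1.25 ± 0.17. Bdh1, an enzyme of ketone body oxidation, rose 2.81-fold. Smaller falls were measured for the alpha myosin heavy chain gene Myh6 (-0.19 ± 0.03), the sarcoplasmic calcium pump gene Atp2a2 (-0.13 ± 0.03), Ppargc1a (-0.42 ± 0.06), Ppara (-0.46 ± 0.07) and Pdk4 (-0.49 ± 0.11), all past adjusted p 0.05. Ppargc1a and Ppara encode regulators of mitochondrial and fatty acid genes, and Pdk4 encodes a kinase that inhibits pyruvate dehydrogenase.

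**Figure D1:**
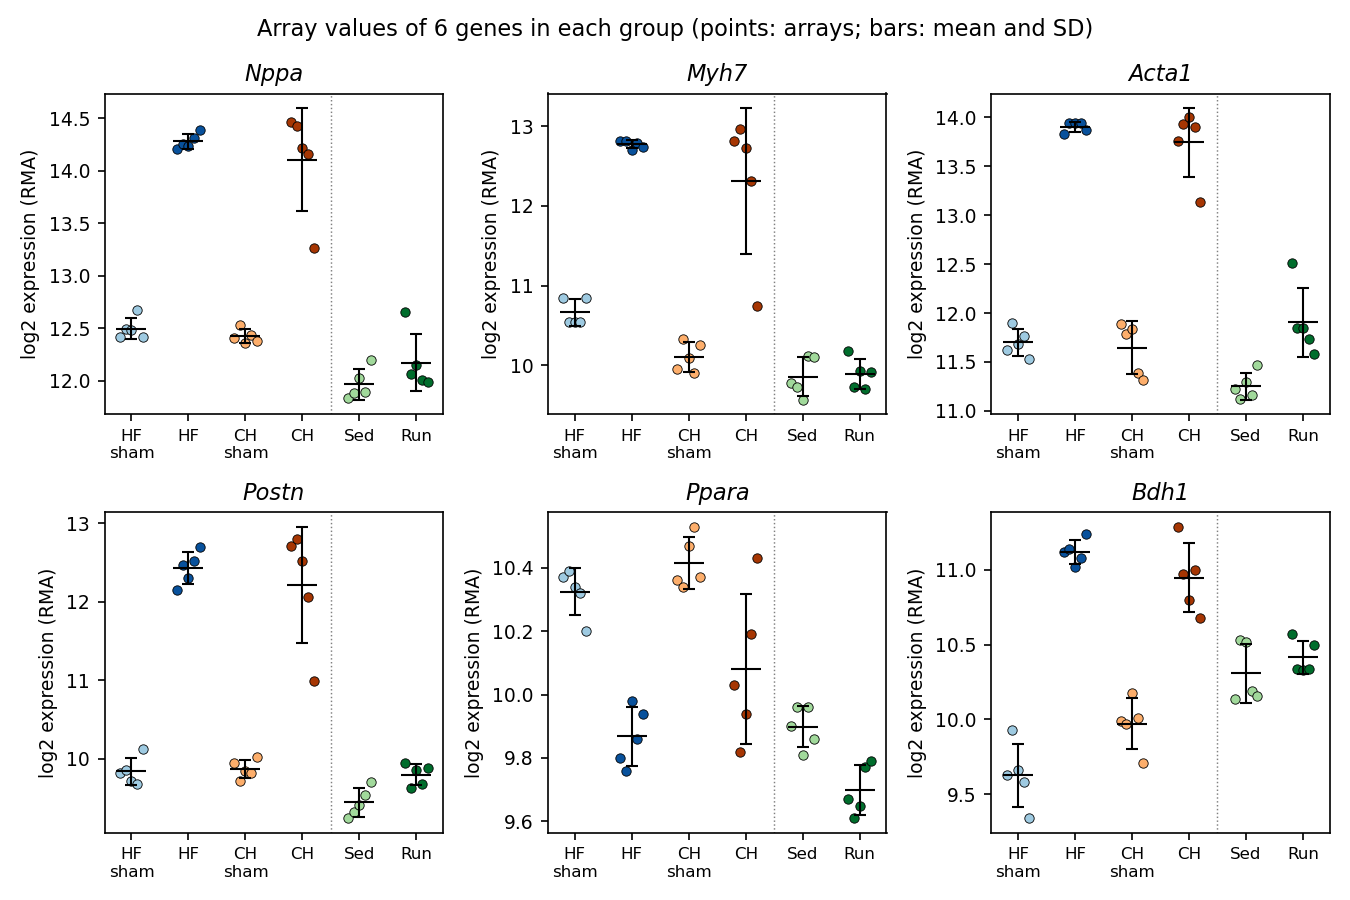
Log2 expression (RMA, vertical axes) of Nppa, Myh7, Acta1, Postn, Ppara and Bdh1 on each array of the 6 groups, with bars for the group mean and SD; the dotted line parts the surgical from the running experiment. Nppa has a mean of 14.28 in HF and 12.50 in HF_sham, and 1 CH array, replicate 5, lies at 13.26, below the other CH arrays.

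In HF, the extracellular matrix list rose as a whole: 33 of 33 measured members rose, with log2 fold changes from 0.16 to 2.59, and Bgn (0.73 ± 0.07) and Ltbp2 (1.59 ± 0.17) were among those with the smallest p (camera adjusted p = 1.61e-30). The adjusted p = 0.154 with an estimated correlation. Of 14 members of the fetal gene programme 11 rose, among them Ankrd1 at 0.91 ± 0.09 and Fhl1 at 0.99 ± 0.11, and 3 did not pass (camera adjusted p = 4.03e-11, and adjusted p = 0.0935 with an estimated correlation). Markers of other cell types rose beside the matrix genes. For fibroblast markers 9 of 14 rose, with Mfap5 at 1.56 ± 0.17 and Pi16 at 0.86 ± 0.10, and for macrophage markers 13 of 17 rose, with the lysosomal protease gene Ctss at 0.69 ± 0.07 and Mrc1 at 0.37 ± 0.06. Camera gave these 2 lists adjusted p of 2.57e-06 and 2.25e-08, and both had adjusted p = 0.154 with an estimated correlation. Interferon response genes rose in 8 of 11 cases, with Ifit3 at 0.81 ± 0.11 (camera adjusted p = 2.57e-06, adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, the risers were 33 for matrix, 11 for the fetal programme (beside 2 fallers), 9 for fibroblast, 14 for macrophage and 10 for interferon genes.

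For fatty acid oxidation in HF, 19 of 25 measured members fell and none rose, with Ech1 at -0.52 ± 0.06 and Acaa2 at -0.47 ± 0.06 (camera adjusted p = 2.06e-14, adjusted p = 0.154 with an estimated correlation). Branched-chain amino acid breakdown had 13 fallers, among them Bckdhb at -0.56 ± 0.06, and 1 riser among 19 (2.25e-08, adjusted p = 0.154 with an estimated correlation). In the oxidative phosphorylation list 22 of 44 fell and 1 rose, with Cox7a1 at -0.25 ± 0.04 and Ndufv1 at -0.24 ± 0.04 (7.78e-08, adjusted p = 0.154 with an estimated correlation). The tricarboxylic acid cycle list had 13 fallers of 20, with Sdhc at -0.30 ± 0.04 (2.57e-06, adjusted p = 0.201 with an estimated correlation). Of 17 mitochondrial regulators 9 fell, with Ppargc1b at -0.47 ± 0.06 (4.66e-05, adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone the fallers were 21 for fatty acid oxidation, 15 for branched-chain amino acids, 24 for oxidative phosphorylation, 14 for the tricarboxylic acid cycle and 10 for the regulators. Cardiomyocyte markers as a list had a mean log2 fold change of -0.01 and did not pass (camera adjusted p = 0.925), with 1 riser, Mybpc3, and 2 fallers, Myh6 and Tnni3, among 14.

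Genes of the ion channel list fell in 12 of 14 cases in HF, all 12 also when adjusted over the list alone (camera adjusted p = 1.61e-09, adjusted p = 0.0935 with an estimated correlation). Among them were the potassium channel gene Kcnd2 at -0.86 ± 0.09 and Kcnip2, which encodes a potassium channel-interacting protein, at -0.63 ± 0.07. Inflammatory cytokine genes had 7 risers of 17, led by Ptgs2 at 0.48 ± 0.10 and Il6 at 0.92 ± 0.20 (0.047, adjusted p = 0.271 with an estimated correlation), and the glycolysis list had 3 risers, including Pfkp at 0.72 ± 0.10, and 8 fallers, including the glucose transporter gene Slc2a4 at -0.51 ± 0.06, among 19 (0.0484, adjusted p = 0.46 with an estimated correlation). The counts were also 7, and 3 and 8, adjusted over the list alone. The call of the glycolysis list ended without HF_sham replicates 1, 2 or 3 or HF replicates 3 or 4 (adjusted p from 0.0531 to 0.085), and that of the cytokine list without HF_sham replicates 2, 4 or 5 or HF replicates 1 or 2 (0.0515 to 0.108). With dim genes left out neither passed (0.114 and 0.299), nor with median centring (0.0573 and 0.0554). The glycolysis call also ended with quantile normalization again (0.0551). Without CH replicate 5, CH_sham replicate 1 and Run replicate 2 together it ended as well (0.0624). The calcium handling list did not pass (0.557), with 2 risers, including Casq2 at 0.29 ± 0.04, and 5 fallers, including Hrc at -0.47 ± 0.06, among 14.

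In all, 4981 of 19938 genes passed adjusted p 0.05 in HF with limma, 2606 higher and 2375 lower, and 411 of them had a fold of at least 1.5 (310 higher, 101 lower). With each array centred on its median 2831 were higher and 1984 lower. The values of the 5 HF and 5 HF_sham arrays did not overlap for 3468 genes, where chance gives 0.794% of genes. All 13 list calls were lost with an estimated correlation, while fry called 22 lists. Fry asks whether a list moves on balance in 1 direction, and not, as camera does, whether it moves more than other genes. Its calls therefore do not offset that loss.

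Pressure overload was then compared with CH_sham to find the genes that differed after aortic constriction. Postn rose 5.09-fold (2.35 ± 0.20, adjusted p = 7.42e-09, n = 5 arrays per group), from 9.87 ± 0.12 (SD) to 12.21 ± 0.74. Thbs4 rose by 2.35 ± 0.28, Myh7 by 2.21 ± 0.24, the collagen cross-linking enzyme gene Lox by 2.20 ± 0.29, Cilp by 2.18 ± 0.25 and Acta1 by 2.10 ± 0.15 log2 units. Ces1d fell 2.6-fold (-1.38 ± 0.17), followed by Mrgprh (-1.04 ± 0.15), Pla2g5 (-1.04 ± 0.11), Phkg1 (-0.97 ± 0.15), Inmt (-0.92 ± 0.15) and Efemp1 (-0.89 ± 0.14). Nppa and Nppb rose by 1.68 ± 0.14 and 1.46 ± 0.17, Col1a1 by 0.67 ± 0.11, Ccn2 by 1.24 ± 0.17 and Bdh1 by 0.98 ± 0.11. Myh6 (-0.15 ± 0.03), Atp2a2 (-0.11 ± 0.03), Ppargc1a (-0.25 ± 0.06) and Ppara (-0.33 ± 0.07) fell, and Pdk4 at -0.11 ± 0.11 did not pass (adjusted p = 0.544). CH replicate 5 lay apart from the other CH arrays for several of these genes: Nppa read 13.26 there, Acta1 13.14 and Pla2g5 10.91.

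In CH, 32 of 33 extracellular matrix genes rose, Col8a1 by 1.82 ± 0.15 and Bgn by 0.62 ± 0.07 (camera adjusted p = 1.24e-31, adjusted p = 0.144 with an estimated correlation). The fetal gene programme had 11 risers, including Ankrd1 at 1.06 ± 0.09, and 1 faller, the smooth muscle actin gene Acta2, among 14 (1.24e-11, adjusted p = 0.0956 with an estimated correlation). Fibroblast markers rose in 7 of 14 cases (0.000263, adjusted p = 0.241 with an estimated correlation), macrophage markers in 10 of 17 (2.73e-07, adjusted p = 0.221 with an estimated correlation) and interferon response genes in 9 of 11 (5.75e-06, adjusted p = 0.227 with an estimated correlation). Among these, Mfap5 rose by 1.42 ± 0.17, Mpeg1 by 0.59 ± 0.09 and Rsad2 by 0.54 ± 0.09. Cell cycle genes rose in 13 of 22 cases, with the mitotic kinesin gene Kif11 at 0.50 ± 0.09 and the spindle protein gene Prc1 at 0.52 ± 0.11 (6.37e-06, adjusted p = 0.241 with an estimated correlation). In HF, 3 of these 22 rose and the list did not pass (0.0622). Inflammatory cytokine genes rose in 6 of 17 cases, led by Ptgs2 at 0.67 ± 0.10 (0.0237, adjusted p = 0.241 with an estimated correlation), and heat shock genes in 4 of 12, led by Hsp90aa1 at 0.84 ± 0.12 (0.0283, adjusted p = 0.241 with an estimated correlation). Adjusted over the list alone the risers were 33 matrix, 11 fetal, 7 fibroblast, 12 macrophage, 9 interferon, 13 cell cycle, 6 cytokine and 4 heat shock genes.

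Fatty acid oxidation in CH had 18 fallers of 25, with Echs1 at -0.31 ± 0.04 and Mlycd at -0.53 ± 0.07 (camera adjusted p = 1.24e-11, adjusted p = 0.227 with an estimated correlation). In oxidative phosphorylation 21 of 44 fell, with Ndufb8 at -0.32 ± 0.05 (2.85e-07, adjusted p = 0.221 with an estimated correlation). Branched-chain amino acid genes had 12 fallers and 1 riser among 19 (4.37e-06, adjusted p = 0.241 with an estimated correlation), with Hsd17b10 at -0.38 ± 0.05. The tricarboxylic acid cycle list had 11 fallers of 20 (0.000148, adjusted p = 0.288 with an estimated correlation) and the mitochondrial regulators 9 fallers and 1 riser of 17 (0.00091, adjusted p = 0.241 with an estimated correlation), with Rxra at -0.35 ± 0.06. Ion channel genes fell in 11 of 14 cases, with the potassium channel genes Kcnd2 at -0.69 ± 0.09 and Kcnh2 at -0.50 ± 0.08 (2.08e-08, adjusted p = 0.144 with an estimated correlation). Adjusted over the list alone the fallers were 19 for fatty acid oxidation, 25 for oxidative phosphorylation, 13 for branched-chain amino acids, 12 for the tricarboxylic acid cycle, 10 for the regulators and 11 for ion channels. Cardiomyocyte markers did not pass (0.991), with a median log2 fold change of 0.01 and a mean of -0.02 that differ in sign.

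In CH the glycolysis list had 2 risers and 7 fallers of 19, with Ldhb at -0.32 ± 0.03 and Pfkp at 0.76 ± 0.10 (camera adjusted p = 0.0334, adjusted p = 0.428 with an estimated correlation), and its call ended without CH_sham replicates 1 or 3 or CH replicates 3 or 5 (0.0517 to 0.0803). Conduction and neural markers had 3 fallers of 6, among them Hcn4 at -0.36 ± 0.06 and Dbh at -0.33 ± 0.06 (0.0496, adjusted p = 0.221 with an estimated correlation), and the call ended without CH_sham replicates 2, 4 or 5 or CH replicates 3 or 4 (0.0514 to 0.114). The circadian clock list had 2 risers and 6 fallers of 16, with the clock output genes Hlf at -0.62 ± 0.10 and Dbp at -0.58 ± 0.12 lower and the core clock gene Arntl at 0.56 higher (0.0334, adjusted p = 0.399 with an estimated correlation), and the call ended without CH_sham replicate 4 (0.0898) or CH replicate 3 (0.0744). Skeletal muscle markers had 5 fallers of 10, led by the fast myosin gene Myh4 at -1.02 ± 0.21 (0.0044, adjusted p = 0.428 with an estimated correlation). The mean log2 value of that list was 7.76 in CH_sham replicate 1 and 7.16 in replicate 2, against 6.78 to 6.90 in the other CH_sham arrays and 6.50 to 6.82 in CH. With CH replicate 5, CH_sham replicate 1 and Run replicate 2 left out together, a choice made after seeing the data, its adjusted p was 0.0526. Counted when adjusted over the list alone, there were 4 risers and 8 fallers for glycolysis, 3 fallers for conduction, 2 risers and 6 fallers for the clock and 8 fallers for skeletal muscle.

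In CH, 4894 of 19938 genes passed adjusted p 0.05 with limma, 2579 higher and 2315 lower, and 345 of them had a fold of at least 1.5 (269 higher, 76 lower). With each array centred on its median 2818 were higher and 1866 lower, and without CH replicate 4 the balance turned (2187 and 2314). The groups did not overlap for 2515 genes, against 0.794% of genes by chance. With the 10 CH and CH_sham arrays fitted alone 3228 genes passed, and all 18 list calls were lost with an estimated correlation. With dim genes left out, the cell cycle (0.551), cytokine (0.705), heat shock (0.108), clock (0.103), conduction (0.106) and glycolysis (0.0778) lists did not pass. The conduction call also ended with quantile normalization again (0.0957). That of glycolysis ended without CH replicate 5, CH_sham replicate 1 and Run replicate 2 (0.131).

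**Figure D2:**
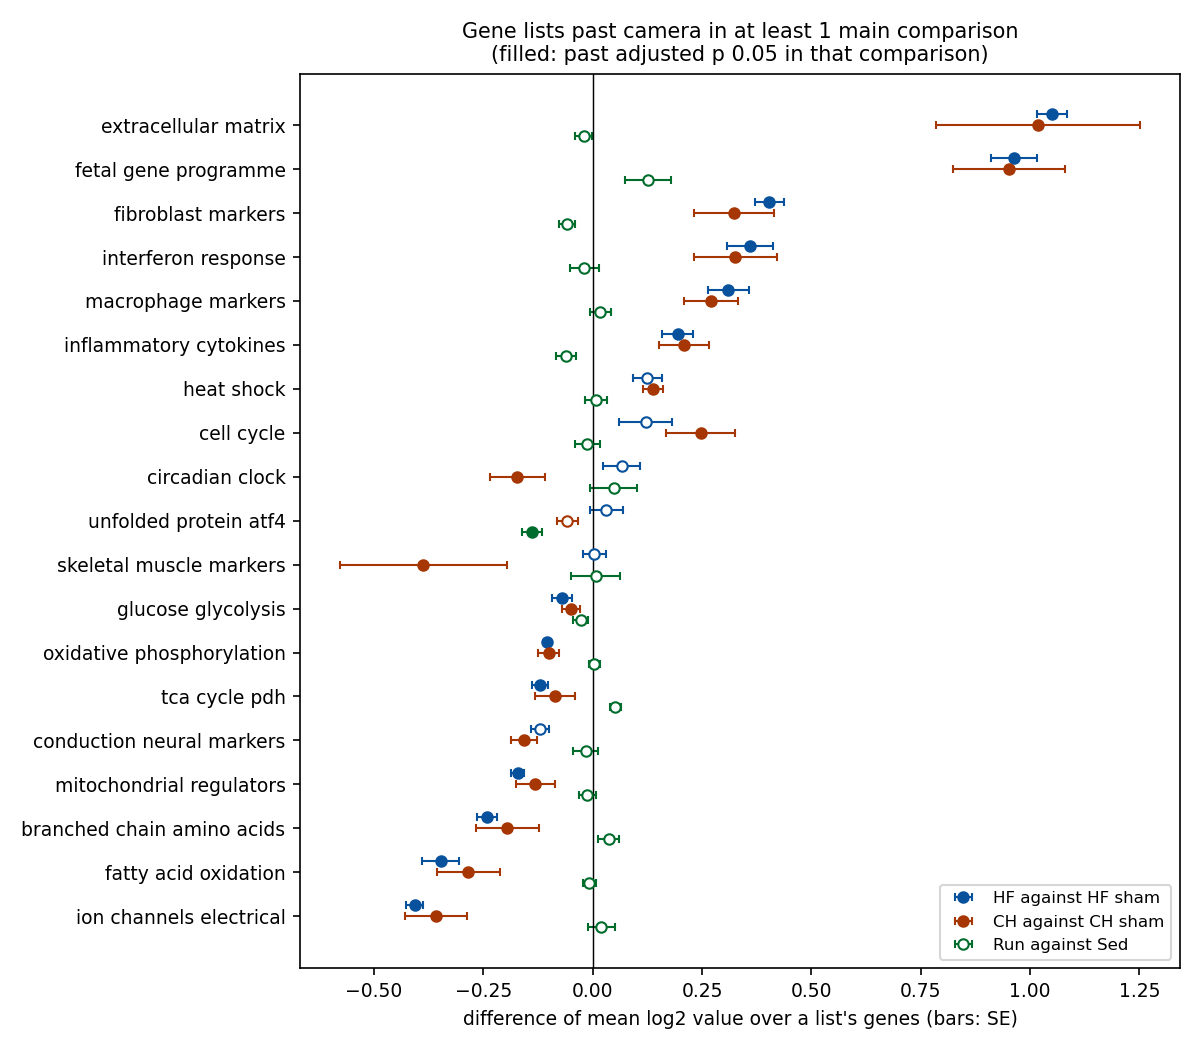
Difference between groups in the mean log2 value over each list's genes (horizontal axis), for the lists called by camera in at least 1 of the main comparisons; points are HF, CH and Run against their controls, bars are the SE of the difference over 5 arrays per group, and filled points passed adjusted p 0.05 in that comparison. The extracellular matrix list differs by 1.05 in HF and 1.02 in CH, and the unfolded protein list by -0.14 in Run.

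Wheel running was compared with the sedentary group to find the genes that differed after voluntary training. Ankrd1, a stress-responsive cardiac ankyrin repeat gene, rose 1.41-fold, from 12.48 ± 0.17 (SD) in Sed to 12.98 ± 0.11 in Run (log2 fold change 0.50 ± 0.09, SE, adjusted p = 0.022, n = 5 arrays per group). Lrrc10, a leucine-rich repeat gene of heart muscle, rose by 0.33 ± 0.06, Stx17 by 0.31 ± 0.06 and Krt222 by 0.25 ± 0.04. Among the fallers, Calr and Hyou1, both chaperones of the endoplasmic reticulum, changed by -0.28 ± 0.04 (adjusted p = 0.00156) and -0.34 ± 0.05 (0.00157). Tppp3 changed by -0.36 ± 0.06 (0.00462), Lrrc52 by -0.59 ± 0.12, Fuca2 by -0.26 ± 0.05 and Ssr2, a subunit of the translocon-associated complex of the endoplasmic reticulum, by -0.23 ± 0.05 (each 0.0417). In the cardiac panel, Acta1 at 0.65 ± 0.15 (adjusted p = 0.0741) did not pass, and its Run values included 12.51 on replicate 1 beside a group mean of 11.90. Nor did Nppa (0.21 ± 0.14), Nppb (0.11 ± 0.17), Myh7 (0.04 ± 0.24), Myh6 (0.00 ± 0.03), Atp2a2 (-0.01 ± 0.03), Ppargc1a (-0.15 ± 0.06), Ppara (-0.20 ± 0.07), Pdk4 (-0.33 ± 0.11), Bdh1 (0.11 ± 0.11), Col1a1 (-0.16 ± 0.11), Postn (0.36 ± 0.20) and Ccn2 (-0.14 ± 0.17).

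The unfolded protein and ATF4 list was lower in Run. Of its 19 measured members Calr fell and 18 did not pass over all genes, while 9 fell when adjusted over the list alone. Hspa5, the main endoplasmic reticulum chaperone, measured -0.24 ± 0.05 (adjusted p = 0.0562), the stress transcription factor gene Xbp1 -0.26 ± 0.06 (0.062) and Manf -0.26 ± 0.06 (0.0741). Among genes tied to the transcription factor ATF4, Asns measured -0.25 ± 0.08 (0.34), while Mthfd2 (0.00), Atf4 (-0.01), Trib3 (0.03) and Ddit3 (0.09) lay closer to 0, and none of these 5 passed. Camera gave the list an adjusted p of 1.32e-11, and it also passed with an estimated correlation (0.0128) and with fry (0.000749). The mean of the list was lower in each Run array than in every Sed array, by 0.14 log2 units, and the exact permutation p of 0.00794 is the smallest that 5 arrays against 5 allow. It was 0.151 after adjustment over the 38 lists. No other list passed in Run. The tricarboxylic acid cycle list had the same exact p, at 0.05 log2 units higher in Run, and did not pass with camera (adjusted p = 0.29). Fibroblast markers were lower beside it, by a mean of -0.06 ± 0.02 (exact permutation p = 0.0238, 0.301 after adjustment over the lists), and did not pass with camera (adjusted p = 0.207). In HF the same list had 5 risers, including Mthfd2 at 0.74 ± 0.08 and Asns at 0.34 ± 0.08, and 4 fallers, including Herpud1 at -0.52 ± 0.10 (0.662), and in CH 3 risers and 8 fallers, including Hspa5 at -0.31 ± 0.05 (0.243).

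**Figure D3:**
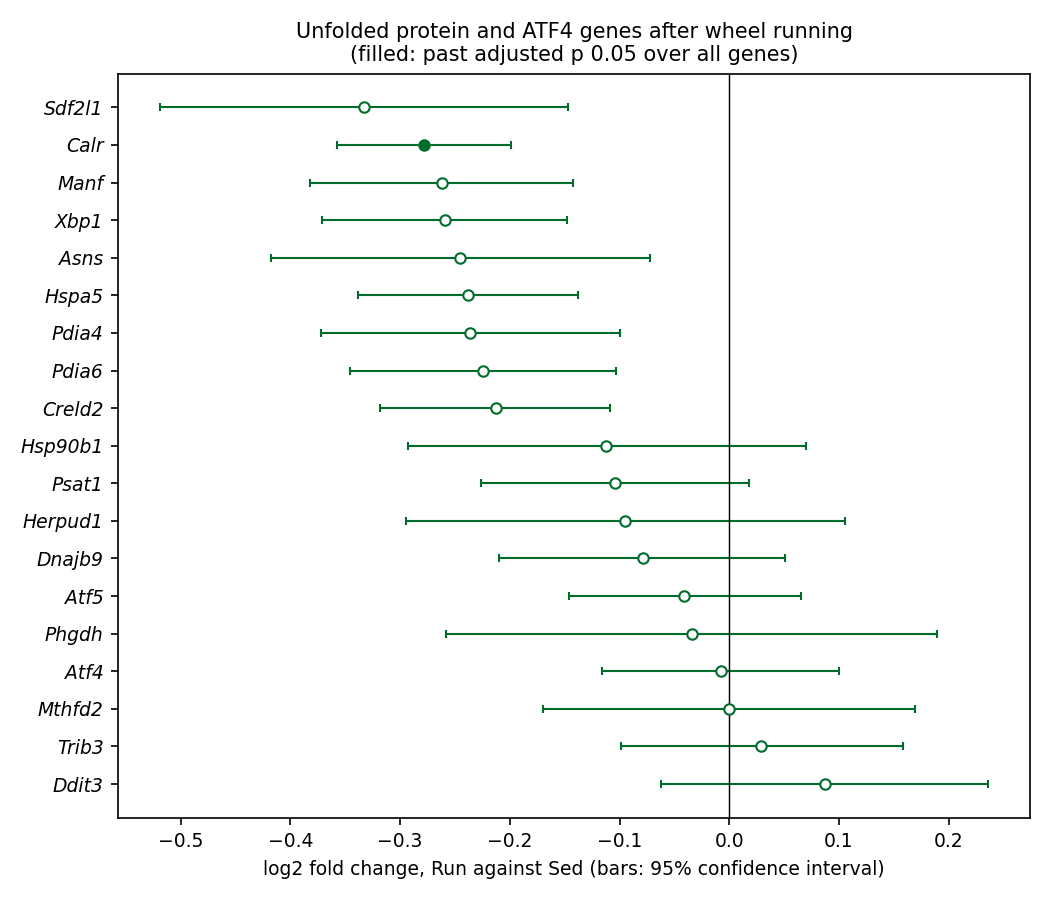
Log2 fold change in Run against Sed (horizontal axis) of the 19 measured genes of the unfolded protein and ATF4 list, with bars for the 95% confidence interval; the filled point, Calr at -0.28, passed adjusted p 0.05 over all genes. Sdf2l1 has a value of -0.33 and Ddit3 of 0.09.

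In total 12 of 19938 genes passed in Run with limma, 4 higher and 8 lower, and 1 of them, Lrrc52, had a fold of at least 1.5. The balance of directions turned in 4 settings, among them array weights (92 higher and 71 lower), the fit without CH replicate 5, CH_sham replicate 1 and Run replicate 2 (9 and 6) and that without Run replicate 2 alone (4 and 3). For 666 genes the groups did not overlap, against 0.794% of genes by chance. The count was 3 without Run replicate 3, 4 without Sed replicates 1, 3 or 4, 5 without Sed replicate 2, 6 without Run replicate 5 and 7 without Run replicates 1, 2 or 4, and 12 without Sed replicate 5. Calr, Hyou1 and Tppp3 passed in all 10 of these refits. Ankrd1 passed in 5 of them and was lost without Sed replicates 1, 2 or 3 or Run replicates 1 or 3 (adjusted p up to 0.106). Krt222 was lost without Sed replicates 1, 3 or 4 or Run replicate 3 (up to 0.094). Stx17 passed in 3, without Sed replicates 2 or 5 or Run replicate 2 (otherwise up to 0.11). Lrrc10 passed in 1, without Run replicate 2 (up to 0.106), and Fuca2 in 1, without Run replicate 1 (up to 0.149). Lrrc52 and Ssr2 passed in 1, without Sed replicate 5 (both up to 0.18). Fitted on the 10 running arrays alone, limma called 0 genes (2169 at an unadjusted p under 0.05), with adjusted p of 0.0532 to 0.0922 for the named genes.

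The effects of HF and CH were set against each other through the difference of the differences, each condition against its own shams. Nppa differed by 0.10 ± 0.20 (95% confidence interval -0.32 to 0.52), Myh7 by -0.10 ± 0.34 (-0.79 to 0.59) and Postn by 0.24 ± 0.28 (-0.33 to 0.82), none past the threshold. Without CH replicate 5 the 3 differences were -0.11 ± 0.13 (-0.38 to 0.17), -0.49 ± 0.17 (-0.84 to -0.15, adjusted p = 0.616) and -0.06 ± 0.17 (-0.41 to 0.28), again not past it. Over all arrays Bdh1 at 0.52 ± 0.15 (0.21 to 0.82, adjusted p = 0.592) and Pdk4 at -0.39 ± 0.16 (-0.71 to -0.06, adjusted p = 0.83) did not pass either. With limma 0 of 19938 genes passed, and 1087 had an unadjusted p under 0.05, where 996.9 are expected by chance. Both effects were higher for 1891 genes and lower for 1562, against 337.1 and 275.8 expected from independent lists, and 4 genes were called in opposite directions against 609.8 expected. Across genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.828 and a Spearman rho of 0.679. Without CH replicate 5, 15 genes passed, among them the clock genes Dbp, Hlf and Per3 with the HF effect above the CH effect, and the immediate-early genes Egr1 and Egr2 and the matrix genes Fmod and Thbs1 with the HF effect below it. These 15 were looked up after their values were seen.

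**Figure D4:**
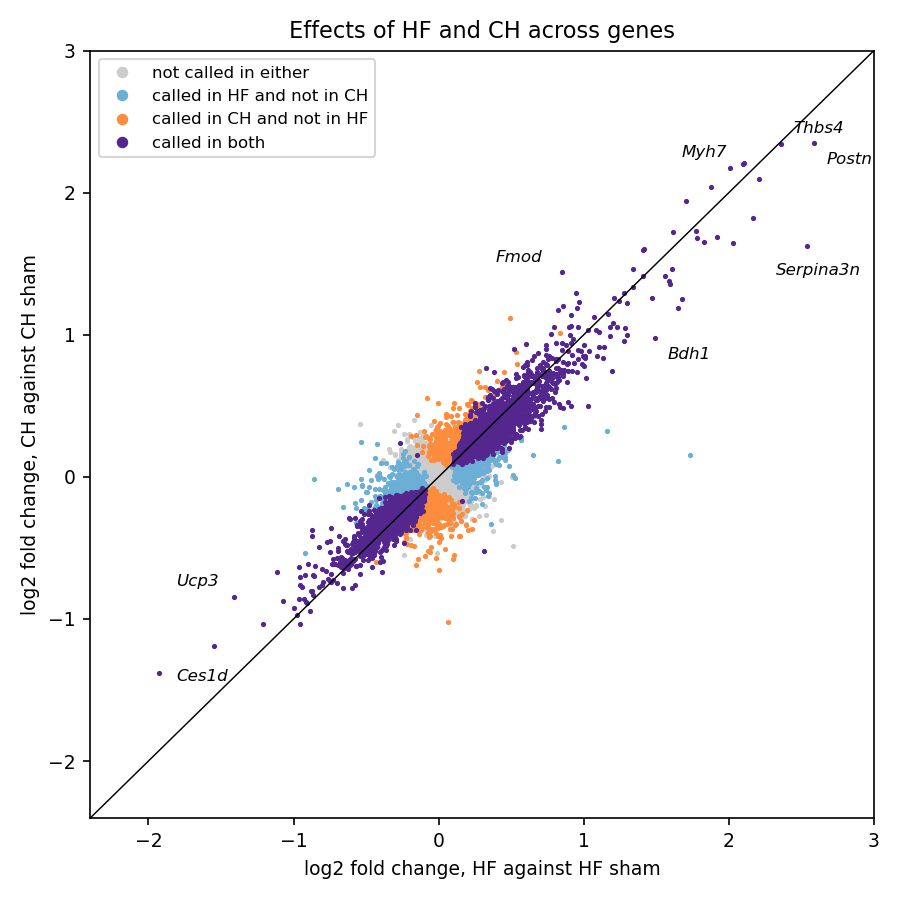
Log2 fold change of each gene in CH against CH_sham (vertical axis) and in HF against HF_sham (horizontal axis), coloured by where the gene passed adjusted p 0.05; the line marks equal effects. Most genes called in both lie near the line, and Serpina3n lies at 2.54 in HF and 1.63 in CH.

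Camera called 8 of 38 lists in the difference between HF and CH, although no single member passed. The circadian clock list was higher in the HF effect, with 7 members higher and 1 lower adjusted over the list alone (adjusted p = 4.91e-06), and the immediate-early list was lower, with 1 higher and 4 lower (4.91e-06). In the effects themselves Nr4a1 fell by 0.86 log2 units in HF and measured -0.01 in CH, Fos fell by 0.63 in HF and measured -0.05 in CH, and Egr2 rose by 0.75 in CH and measured 0.28 in HF. Skeletal muscle markers (4.91e-06), the unfolded protein list (0.001), atrial markers (0.00465) and smooth muscle and pericyte markers (0.00717) were higher in the HF effect, while cell cycle genes (0.000217) and fatty acid oxidation (0.0479) were lower. The skeletal muscle difference came with the raised CH_sham replicates 1 and 2 (7.76 and 7.16), while HF (6.62 to 6.74) and HF_sham (6.65 to 6.72) hardly differed. Of the first 4 of these lists 2, 0, 1 and 1 members were higher adjusted over the list alone, and of the last 2 lists 0 members were lower. All 8 calls were lost with an estimated correlation (adjusted p = 0.273 for the clock, 0.306 for the immediate-early, unfolded protein, atrial and smooth muscle lists, 0.33 for skeletal muscle, 0.554 for cell cycle and 0.919 for fatty acid oxidation), and fry called 0 lists. The call for atrial markers ended without HF replicate 5 (0.051), and that for fatty acid oxidation without HF_sham replicates 1, 4 or 5, HF replicates 4 or 5, CH_sham replicate 1 or CH replicates 4 or 5 (0.0536 to 0.994). With dim genes left out the cell cycle (0.0606), atrial (0.0515) and fatty acid oxidation (0.0649) calls ended. That for fatty acid oxidation also ended with quantile normalization again (0.0993) and median centring (0.0544).

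The HF effect exceeded the Run effect for Serpina3n by 2.80 ± 0.47 log2 units (SE, adjusted p = 0.000243), Thbs4 by 2.41 ± 0.40, the protease inhibitor gene Timp1 by 2.27 ± 0.36, Postn by 2.23 ± 0.28 and Cilp by 2.07 ± 0.35. It lay below the Run effect for Ces1d (-1.78 ± 0.23), Pla2g5 (-1.22 ± 0.15), Ucp3 (-1.09 ± 0.30), Phkg1 (-1.0 ± 0.22) and Rgs7 (-0.99 ± 0.17). In this difference the matrix list had 29 of 33 members higher (camera adjusted p = 3.01e-35, adjusted p = 0.1 with an estimated correlation) and fatty acid oxidation 19 of 25 lower (1.14e-15, adjusted p = 0.102 with an estimated correlation). The fetal programme, with 11 of 14 higher, and the ion channels, with 10 of 14 lower, were the 2 of 15 called lists that also passed with an estimated correlation (both 0.0455). For these 4 lists the counts were 33, 22, 11 and 11 adjusted over the list alone. With limma 2223 genes differed, 1137 higher and 1086 lower in the HF effect. This balance turned with quantile normalization again (1153 and 1196), without dim genes (1188 and 1260) and with array weights (1512 and 1583).

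For the CH effect minus the Run effect, Thbs4 differed by 2.39 ± 0.40 (adjusted p = 0.000426), Cilp by 2.24 ± 0.35, Myh7 by 2.17 ± 0.34, Lox by 2.13 ± 0.40 and Postn by 1.99 ± 0.28. Negative differences were led by Ces1d (-1.23 ± 0.23), Pla2g5 (-1.05 ± 0.15), Myh4 (-1.03 ± 0.30), Mrgprh (-1.03 ± 0.21) and Phkg1 (-0.99 ± 0.22). Myh4 belongs to the skeletal muscle markers, whose mean was raised in CH_sham replicates 1 and 2 (7.76 and 7.16). Without CH replicate 5, CH_sham replicate 1 and Run replicate 2, that list did not pass in this difference (camera adjusted p = 0.215). The matrix list had 30 of 33 members higher (camera adjusted p = 2.4e-37, adjusted p = 0.0821 with an estimated correlation), the fetal programme 10 of 14 higher (6.65e-13, adjusted p = 0.0599 with an estimated correlation) and fatty acid oxidation 13 of 25 lower (6.65e-13, adjusted p = 0.152 with an estimated correlation). These counts were 33, 11 and 20 adjusted over the list alone. With limma 1705 genes differed, 864 higher and 841 lower in the CH effect. This balance turned in some settings, among them array weights (2765 genes, 1310 higher and 1455 lower). None of the 17 list calls held with an estimated correlation. The log2 fold changes of Run correlated across genes with those of HF at r = 0.241 (rho 0.206) and with those of CH at r = 0.275 (rho 0.228). Of the 12 genes called in Run, 5 were called in the same direction in HF and 7 in CH, with 1 opposite in each, Fuca2, which rose in HF and CH.

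The sham groups were compared with each other because both held sham-operated mice of the same age. With limma 0 of 19938 genes passed, with 1653 at an unadjusted p under 0.05 against 996.9 expected by chance. The count was 4 without CH_sham replicate 1, 2 without CH_sham replicate 5 and 1 without CH_sham replicate 4 or HF_sham replicate 5. Camera called 4 lists: skeletal muscle (4.56e-10) and clock genes (0.00152) higher in CH_sham, and fatty acid oxidation (0.0221) and thymus markers (0.043) lower, with 8 skeletal muscle members and 5 clock members higher and 2 clock members lower when adjusted over the list alone. With an estimated correlation none held (adjusted p = 0.446, 0.599, 0.941 and 0.875). For skeletal muscle, CH_sham replicates 1 and 2 stood apart at 7.76 and 7.16, against 6.78 to 6.90 in the other CH_sham arrays and 6.65 to 6.72 in HF_sham. The fatty acid oxidation call ended without HF_sham replicate 5 (0.129) or CH_sham replicate 1 (0.318), and the thymus call without HF_sham replicates 1, 3 or 5 or CH_sham replicates 2 or 3 (0.0769 to 0.491).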

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

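Chosen only after the result was seen were the tests of a sham label, of single arrays, of clock phase in HF and CH, and of fibroblast content. In each group of 5 arrays, the highest or lowest array was marked when its gap to the nearest other array exceeded 0.71 of the group's range. This was done for 39 genes named by size or from the panel, 19 gene lists and 1 further score. It marked 35 of 354 groups, where chance gives about 1 in 20, or 17.7. For the other 159 named genes 59 of 954 groups were marked, against 47.7 by chance. CH replicate 5 was marked 7 times, for Acta1 (13.14), Col8a1 (9.85), Pla2g5 (10.91), Nppa (13.26) and the cytokine (6.85), fibroblast (9.84) and macrophage (8.39) lists. CH_sham replicate 1 was marked 5 times, for Col1a1 (9.57) and the fatty acid oxidation (12.18), tricarboxylic acid cycle (12.39), branched-chain amino acid (10.5) and heat shock (11.34) lists. HF_sham replicate 5 was marked for Col1a1 (9.22), Tppp3 (9.46), Ssr2 (10.57), glycolysis (11.71) and extracellular matrix (9.09), and HF replicate 1 for Col8a1 (10.89), Phkg1 (8.26), interferon response (9.18) and cell cycle (6.86). Run replicate 1 was marked for Acta1 (12.51), Ces1d (10.55), Nppa (12.65) and Ankrd1 (13.16), and HF replicate 3 for ion channels (9.17) and the tricarboxylic acid cycle (12.42). Single marks were Nppa in HF_sham replicate 4 (12.67), Atp2a2 in Sed replicate 5 (14.13), Stx17 in Sed replicate 1 (8.49), macrophage markers in Sed replicate 4 (8.02), Ppargc1a in Run replicate 5 (11.11), Krt222 in Run replicate 3 (8.99), Hyou1 in Run replicate 4 (8.88) and skeletal muscle markers in Run replicate 2 (6.71).

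CH replicate 5 lay between the sham arrays and the other CH arrays. Of the 411 genes changed at least 1.5-fold in HF, 404 differed enough between CH_sham and the other CH arrays to place it, and over these its median position was 0.333, with 0 at the CH_sham mean and 1 at the mean of the other CH arrays. The shams lay from -0.051 to 0.03, which argues against a sham array under a CH label, and the other CH arrays from 0.792 to 1.146. A mixture of CH and sham RNA would give 1 share for risers and fallers, and the shares were 0.24 and 0.449. Their difference of -0.209 lay outside the bound set in advance, -0.139 to 0.11 in the other CH arrays, but by less than the SD of those (0.105). That margin was added after the value was seen, and with it a mixture and a weaker response to constriction, which was not tested, cannot be told apart.

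The difference between the HF and CH effects passed camera for 8 lists: fatty acid oxidation (0.0479), cell cycle (0.000217), unfolded protein (0.001), clock (4.91e-06), immediate-early (4.91e-06), smooth muscle (0.00717), atrial (0.00465) and skeletal muscle (4.91e-06) genes. None of the 8 passed with an estimated correlation (smallest adjusted p = 0.273) or with fry. The atrial call ended without HF replicate 5 (0.051), and the fatty acid oxidation call without any of 8 arrays (0.0536 to 0.994). With dim genes left out these calls and that for cell cycle genes (0.0606) ended. For the clock and immediate-early lists the camera call at the preset correlation held without any single array. The highest adjusted p without 1 array was 0.000241 and 0.000327, both without CH replicate 3. Since both lists failed with an estimated correlation on all arrays, these refits cannot settle whether a single array lies behind the difference. A difference in the clock phase at which hearts were collected is a candidate explanation for the clock list. Genes peaking with Dbp minus genes peaking opposite differed between the effects by 0.74 ± 0.24 (SE, exact permutation p = 0.0199, 20 arrays), and between the sham groups by 0.45 ± 0.15 (exact p = 0.0159). Of the 2 parts of the difference between the effects, the 7 genes peaking with Dbp gave 0.45 ± 0.14 (exact p = 0.0155), which largely repeats the list call. The 3 genes peaking opposite gave -0.28 ± 0.11 (0.0569) and did not pass. These permutations within both experiments test for no effect in either, so a CH effect alone can give a small p. It was -0.71 ± 0.20 in CH (exact p = 0.0317) and 0.03 ± 0.13 in HF (exact p = 0.865), and CH replicate 5 at 1.43 lay apart from the other CH arrays, at 0.48 to 0.70. The collection time is not given in the sources used here, and an effect of constriction on the clock stays open beside it.

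The unfolded protein list was lower in Run, and its highest camera adjusted p at the preset correlation without 1 array was 3.04e-08. Fewer fibroblasts were predicted to lower fibroblast markers at least as much, and these measured -0.06 ± 0.02 (exact p = 0.0238) against -0.14 ± 0.02 for the list (exact p of the difference 0.00794, the smallest possible). The list thus fell more than these markers. The prediction assumes that both sets of genes follow cell content equally, and other cell types were not compared. A change in cell make-up is therefore not excluded. The clock contrast differed by 0.10 ± 0.14 between Run and Sed (exact p = 0.611), an error too wide to tell, so another clock phase and an effect of running cannot be told apart by it. Of 100 splits of the 10 arrays 1, the real one, gave this list an unadjusted camera p as small as 3.47e-13, and the lowest of the others was 5.59e-12. This was the only list called in the real split, and the smallest p over all 38 lists was not compared between splits. At least 1 list was called in 79 of the 100 splits, the real one included. Camera at the preset correlation thus often calls a list without a real grouping, and these splits cannot settle chance for a list picked this way.

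The real split was compared with others of the same arrays, 100 in all with the real one included. For HF 1 split gave as many as the 4981 genes (highest other 1908) and for CH 1 as many as 4894 (2365). For Run 1 gave as many as 12 (2). Only the real split reached each of these counts, which bears on the counts and not on single genes. Fitted on the running arrays alone, limma called 0 genes in Run. For HF minus Run 1 gave as many as 2223 (1) and for CH minus Run 3 as many as 1705 (2294). These splits relabel both experiments and so test for no effect in either. An HF or CH effect alone can give such counts, so they cannot settle whether it differs from the Run effect. Of the list counts, 2 splits gave as many as the 18 of CH (highest other 18), so splits seldom reached it. But 22 gave as many as the 13 of HF (19) and 79 as many as the 1 of Run (7), where chance stays open. Among the HF splits were ones that exchanged 1 array between the groups and gave 16 and 14 lists. These left most of a real effect in place, so the HF list count cannot decide about chance. For HF minus CH and for the sham groups limma called 0 genes (1087 and 1653 at an unadjusted p under 0.05), a count that all 100 splits reach whatever the data, so these comparisons say nothing about chance. The highest other counts were 2671 and 286. The splits with 1908 genes in HF and 2365 in CH exchanged 1 array between the groups, and that with 2294 exchanged 0 CH arrays and 3 Run arrays, so most of a real effect was left in each of these 3. The split with 2671 exchanged 4 of the 5 HF arrays and 1 CH array, which turns the HF effect round so that it adds to the CH effect. The split with 286 genes exchanged 1 array between the sham groups, which points to a structure among the sham arrays, and its source was not tested.

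Measurements outside the gene tests also passed. Among those with no symbol listed 824 passed in HF, 899 in CH and 4 in Run, and among those with several symbols 253 in HF and 280 in CH.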

How the results depend on the processing

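The setting without CH replicate 5, CH_sham replicate 1 and Run replicate 2, and no other, was chosen among these tests only after the result was seen. Genes past the threshold in HF went from 4981 to 3268 at adjusted p 0.01 and 411 with a fold of at least 1.5, and in CH from 4894 to 3086 and 345, and to 3228 with its own arrays alone. The 12 genes of Run became 26 with quantile normalization again, 6 with median centring (3 higher and 3 lower, against 4 and 8), 60 without dim genes, 37 with trend and robust estimation, 163 with array weights (92 higher and 71 lower), 15 without the 3 arrays (9 and 6), 47 with the replicate block (30 and 17), 3 at adjusted p 0.01, 1 with the fold and 0 by limma with its own arrays alone (2169 at an unadjusted p under 0.05). Leaving out 1 array gave 3 (Run replicate 3) to 12 (Sed replicate 5). For HF minus CH, 0 became 2 without dim genes, 5 without the 3 arrays, 1 with its own arrays and 15 without CH replicate 5, and stayed 0 without any other array. HF minus Run went from 2223 to 1179 and 341 at the same stricter thresholds, and CH minus Run from 1705 to 737 and 262, and to 2765 with array weights. The sham groups went from 0 to 3 with all measured positions, 3 with array weights, 3 without the 3 arrays and 4 without CH_sham replicate 1. Lists called with an estimated correlation were 0 of 13 in HF, 0 of 18 in CH, 0 of 8 in HF minus CH, 2 of 15 in HF minus Run, 0 of 17 in CH minus Run and 0 of 4 between shams. Fry called 22 in HF, 0 in HF minus CH and 0 between shams, and without dim genes 11 passed in CH, 4 in HF minus CH and 2 between shams. Without 1 array, Run had 1 to 2 lists, HF minus CH 6 to 13 and the shams 2 to 6. The correlation of HF with CH went from 0.828 to 0.922 without dim genes and 0.913 over genes called in either comparison. Over such called genes that of HF with Run went from 0.241 to 0.362 and that of CH with Run from 0.275 to 0.418. Without dim genes these 2 were 0.303 and 0.354. Called genes were chosen by the effects that are correlated, so a higher r over them can come from the choice. The 3453 genes shared by HF and CH became 2222 at adjusted p 0.01, the 5 of HF and Run 2, or 25 without dim genes, and the 7 of CH and Run 2, or 34. The balance of 1137 higher and 1086 lower for HF minus Run turned with quantile normalization again (1153 and 1196), without dim genes (1188 and 1260) and with array weights (1512 and 1583). That of 864 and 841 for CH minus Run turned in the same settings (917 and 943, 968 and 1056, 1310 and 1455), with trend and robust estimation (972 and 975), and without CH_sham replicates 1 (793 and 809) or 5 (773 and 905), CH replicate 4 (769 and 983), Sed replicate 4 (707 and 711) or Run replicates 2 (713 and 744) or 5 (761 and 779). That of CH turned without CH replicate 4 (2187 and 2314), and that of Run also without Run replicate 2 (4 and 3). The labels give replicate numbers no shared source, and the bound for pairing, every pair correlating over 0.1, was not met, with 7 of 15 pairs over it (-0.036 to 0.259). As a hint of shared structure, 13 of 15 correlations were above 0 and 8 of 15 arrays correlated best with their own number, where chance gives 3. With the replicate block the glycolysis list did not pass in HF (adjusted p = 0.08, 4.64e-11 to 0.46 over its alternatives) or CH (0.0634, 9.17e-11 to 0.428), nor did conduction markers in CH (0.0634, 2.66e-05 to 0.221). Lists that passed with the block alone among these 2 fits were fibroblast markers for HF minus CH (0.0469, 0.0061 to 1), smooth muscle markers for HF minus Run (0.0378, 0.018 to 0.289) and unfolded protein genes for CH minus Run (0.0409, 0.00886 to 0.447). The ranges of lists include fry in the form that counts changes in either direction. Their lower ends therefore need not mean a shift of the list in 1 direction. In Run, Hspa5 (0.0349, 0.00464 to 0.146), Xbp1 (0.0404, 0.00934 to 0.18) and Acta1 (0.0404, 0.0105 to 0.202) passed with it. A stricter threshold lowers a count by construction, and for the other results that moved the cause was not tested.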

Other observations

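All observations here rest on tests chosen only after the result was seen, apart from the tests of single genes. Lcn2, which encodes a secreted iron-binding lipocalin, rose by 1.73 log2 units in HF, to 10.01 ± 1.23 (SD, n = 5), and measured 0.16 in CH, and the difference of 1.57 ± 0.47 did not pass (adjusted p = 0.622). Myh4 averaged 6.96 ± 0.84 (SD) in CH_sham against 5.94 ± 0.17 in CH, 5.78 ± 0.10 in HF_sham and 5.85 ± 0.13 in HF, so its fall in CH rests on the level of its shams.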
